A study of Caenorhabditis japonica with 3 samples.

How the data were processed

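The measurements are read counts from single embryos of the nematode *Caenorhabditis japonica*, made with CEL-Seq, a method that tags the polyA RNA of each embryo with its own barcode, pools the barcoded embryos, amplifies the pool and sequences the 3′ ends of the transcripts. The labels describe 3 pooled libraries. The first holds embryos of 1, 2 and 4 cells and embryos from 10 to 130 minutes after the 4-cell stage, the second those from 140 to 290 minutes and the third those from 300 to 430 minutes, at steps of 10 minutes. These libraries are called early, middle and late. The deposited table gives 46 embryos, 16 early, 16 middle and 14 late, and each of its 46 embryo columns was matched to its time, barcode and library through the deposited sheet of embryos. Each time has 1 embryo. For 330 and 340 minutes the labels name extra embryos, but the table has 1 column for each of these times, so no repeat embryos could be compared. These 2 columns carry the suffixes #1 and #2 and the barcodes 15 and 16 in place of 4 and 5. The sources do not explain the suffixes, so which of the embryos they hold is not certain.

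The authors deposited whole-number read counts per 3′ end peak of a gene, with a row of total counts per gene, and no normalization is stated in the file headers. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3. The role of each tool, the genome build, the annotation, the peak caller and its thresholds are not given in the sources used here. The table holds 3955 genes and 4619 peaks. Each gene has at least 1 peak, each peak has at least 98 reads over the embryos and at least 4.04% of its gene's reads, so the table is a selected part of each library and its totals are not the full sequencing depth. The location of a peak is a number within its gene whose origin and direction are not stated. Peaks are therefore named here as having a higher or lower location, and not as proximal or distal. The sources name no molecular identifiers, so reads that are PCR copies of 1 molecule may be counted more than once, and the counting intervals and lower bounds below cover counting error only.

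The reads in the listed genes ran from 1719 to 454691 per embryo, with a median of 61827. The limit for shallow embryos, 0.25 of the median, is 15457 reads, and 14 embryos lay below it. The genes carry identifiers of the form used for this species and no names. The files pair none of them with a gene symbol and no reference was given, so the 20 gene lists fixed before the data were examined matched 0 genes and no list test was run. By the rule for named genes, fixed at the same time, each comparison names at most 2 genes that rose and 2 that fell: those with the largest positive and negative log2 fold change or slope among genes at an adjusted p under 0.05 with a mean of at least 20 counts per 1000000 reads (CPM) over the embryos compared.

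Gene totals were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test on the counts as deposited, after filterByExpr, which left 1656 genes holding 83.8% of the reads, and scaling with TMM factors. CPM values are relative to the total of these genes, divided by the TMM factors. Adjusted p-values are Benjamini-Hochberg values over the genes, with a threshold of 0.05, and the tests are two-sided. The replicate is the embryo, a separate animal, so the p-values measure the spread between embryos, which includes their difference in age. In a single fit, the windows were compared as groups of embryos. A second fit gave each library its own intercept and slope on embryo position, which counts 1 step per cell stage up to the 4-cell stage and 1 step per 10 minutes after it. Another fit tested a natural cubic spline of position with 4 degrees of freedom over the whole course, and the last added the library to that spline, to find genes with a step at a library border. Library and time window cannot be told apart in this design, since each library holds 1 window. Position within the early and the middle library also cannot be told apart from barcode number, which ascends with time in the early library and descends in the middle one.

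Principal components were taken from the log2 CPM of the 1000 most variable genes, with a prior count of 2. Correlations of component 1 with position were tested with 100000 permutations. Folds for genes with few reads in a window were also taken from reads summed over the window's embryos, which gives deep embryos more weight. A window with 0 reads of a gene was set to 3 counts over the whole window, giving a lower bound, and other ratios have a 95% exact counting interval.

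The use of alternative 3′ end peaks was tested in genes with at least 2 peaks of 10% or more of the gene's reads. For each such peak, its share of the gene's total reads was fitted by quasi-binomial logistic regression on position, over embryos with at least 5 reads of the gene, where at least 10 embryos had them. A first version with the same dispersion at every depth gave too many false calls on simulated data. It was replaced by weights that let the overdispersion grow with the reads per embryo (Williams' method), before any result of the earlier version was used.

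The tests were checked on simulated counts made from the means, spread and library sizes of these embryos. Among the 1656 genes, the comparison of middle with early embryos found 77% of genes changed 2-fold and 100% of those changed 4-fold, and 2.75% of its calls were false. The simulated spread was taken after a spline of position was removed, and the simulated levels were flat within each window. The real comparison of windows includes differences in age, so its power and its share of false calls may differ from these values. For a slope that reaches 4-fold over a library, 17% were found in the early library, 29% in the middle and 8% in the late one. The spline found 78% of the 4-fold courses, whereas the test of a step at a border found 2% of the 4-fold steps, so that test has almost no power. Among the 959 peaks, the usage test found 51.5% of the 4-fold changes in odds and 89.8% of the 16-fold ones, with 2.80% false calls. The simulated overdispersion had the form that Williams' weights assume. In the real peaks the fitted value varied, with a median of 0.031 and 0.33 for 1 peak of CJA14647, so the share of false calls there may differ.

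The alternatives were other scalings (DESeq2 size factors within edgeR, library size alone), no filter or a mean of 20 CPM, DESeq2 1.42.0 and limma-trend 3.58.1 on log2(CPM + 1), fits without shallow embryos, without the embryos of 1, 2 and 4 cells or without those at 330 and 340 minutes, 8 embryos on each side of a border, splines of 3 and 6 degrees of freedom, the library as a covariate and rank correlations. They were listed before the data were examined. TMM with singleton pairing and 3 settings of the usage test (shares of the reads inside peaks, peaks at least 100 apart, and no embryos of 1, 2 and 4 cells) were added after seeing the data, as were all settings for differences between slopes and for the shapes of courses.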

Results

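Single embryos of *C. japonica*, a nematode with males and females that is related to *C. elegans*, were sequenced at 46 points from the 1-cell stage to 430 minutes after the 4-cell stage. The series is a developmental time course, and the questions it addresses are which transcripts change in level between and within the sampled windows and how the use of alternative 3′ ends changes with time. The early library held 16 embryos with a median of 46770 reads (range 1890 to 404701), the middle library 16 embryos with a median of 80479.5 (1719 to 454691), and the late library 14 embryos with a median of 73813 (2305 to 354620). Of the 14 embryos below 0.25 of the overall median, 5 were early, 4 middle and 5 late. The highest Pearson correlation between any pair of embryos was 0.93, so no library was present in duplicate. The files give genes by identifier only, and no gene is described here by function.

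**Figure D1:**
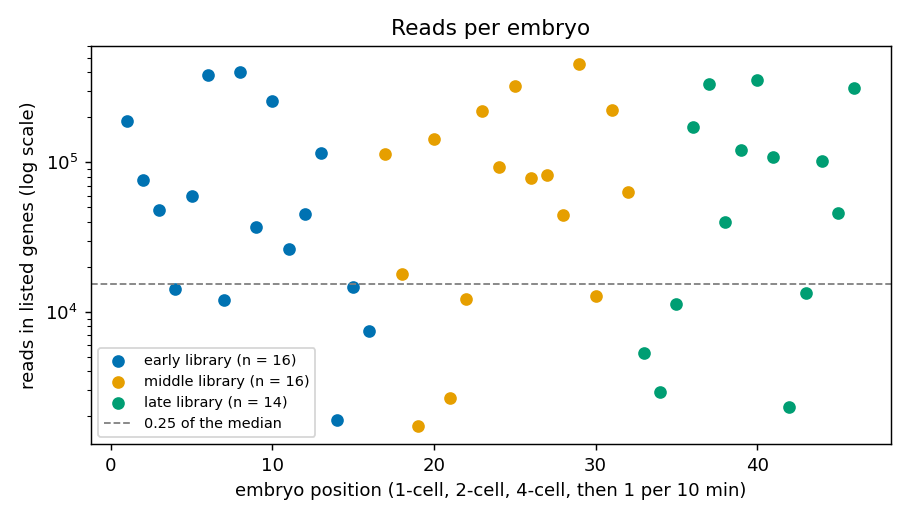
Reads in the listed genes of each embryo (log scale) against embryo position, coloured by library, with a dashed line at 0.25 of the median. Embryos below the line occur in each library, 5 early, 4 middle and 5 late.

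The main axis of variation followed developmental time. Component 1 held 40.6% of the variance and rose with embryo position over the 46 embryos, with Spearman's rho 0.93 and Pearson's r 0.95 (permutation p = 1e-05 for both, the smallest 100000 permutations can give). The 4 rank correlations, over all embryos and within each library, had adjusted p-values between 2e-05 and 0.56. Within the middle library rho was 0.93 and r 0.93 (n = 16, permutation p = 1e-05 for both, the smallest they can give), and r was 0.91 without the earliest and the latest embryo. Within the early library component 1 did not rise or fall steadily with the order of the embryos: rho was -0.16 (permutation p = 0.56) and r -0.15 (permutation p = 0.59, n = 16), and r was -0.29 without the 2 embryos farthest from the middle of the window. The score went from -37.2 in the 1-cell embryo to -48.5 at 60 minutes, then to -40.1 at 100, -45.9 at 110 and -36.3 at 130 minutes. These correlations can miss a curved course, which was not tested. Within the late library rho was 0.65 (n = 14, permutation p = 0.013, adjusted p = 0.018), but r was 0.50 (permutation p = 0.070) and fell to 0.39 without the 2 embryos farthest from the middle of the window. Component 2 held 16.9% of the variance and followed depth: its correlation with the log2 number of reads was rho -0.83 and r -0.86 over 46 embryos (permutation p = 1e-05 for both, the smallest they can give), and r was -0.83 without the 2 embryos farthest from the median depth.

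**Figure D2:**
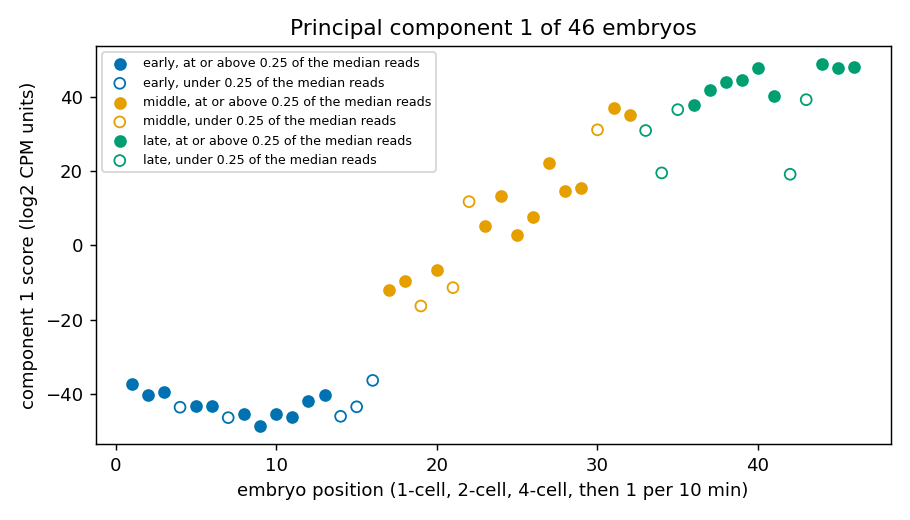
Component 1 score of each embryo against embryo position, coloured by library, with open circles for embryos under 0.25 of the median reads. Scores show no steady rise through the early library, where they dip at 60 minutes, rise through the middle library (rho 0.93) and rise less regularly in the late one (rho 0.65).

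Between the early and the middle window, transcripts absent from the first embryos appeared and abundant early transcripts were lost. CJA43237 had 0 reads in the 16 early embryos and 922 ± 810 CPM (SD, n = 16) in the middle ones, which puts its summed reads at least 433-fold higher in the middle window. CJA03873 had 2 reads in the early library and rose to 1233 ± 1790 CPM (SD, n = 16), a ratio of summed reads of 851 with a counting interval from 235 to 7031. In the other direction, CJA11400 fell from 3418 ± 4291 to 18.9 ± 21.5 CPM (SD, n = 16 each), a log2 change of -7.24 ± 0.65 (SE), and CJA33872 fell from 1283 ± 1282 to 6.34 ± 14.9 CPM (SD, n = 16 each), a log2 change of -7.22 ± 0.59 (SE). The edgeR adjusted p-values of the 4 genes lay between 2.36e-14 and 4.66e-13. Of 1656 genes tested, 1003 (60.6%) changed, with 579 higher and 424 lower in the middle window, and 448 of the rises and 321 of the falls were at least 2-fold. The split into rises and falls depended on the scaling and on the embryos used: DESeq2 size factors, which rest on the few genes with no zero in any embryo, moved the median log2 change of all genes from 0.16 to -0.49 and gave 365 higher and 750 lower, and library size alone gave 513 and 525. With TMM but without the embryos at 330 and 340 minutes, which enter only the shared filter, scaling and dispersion of this comparison, rises were 47.4% of the calls against 57.7%. The count of changed genes was 484 with limma-trend, 1508 without the shallow embryos, 2309 without the low-count filter and 168 with the 8 embryos on each side of the border, and a difference between the 2 libraries cannot be told apart from time here.

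Between the middle and the late window fewer genes changed. CJA04342 rose from 22.3 ± 55.5 (SD, n = 16) to 3320 ± 4263 CPM (SD, n = 14), a log2 change of 6.67 ± 0.62 (SE), and CJA06186 rose from 36.3 ± 69.3 (SD, n = 16) to 1845 ± 2022 CPM (SD, n = 14), a log2 change of 6.32 ± 0.69 (SE). Both were nearly absent before: CJA04342 had 2 reads and CJA06186 had 0 reads in the early embryos. CJA11892 fell from 1111 ± 1504 (SD, n = 16) to 16.8 ± 34.1 CPM (SD, n = 14), a log2 change of -6.06 ± 0.94 (SE). CJA05571 fell from 294 ± 360 CPM (SD, n = 16) to 3 reads in the whole late library, a ratio of summed reads of 153 with a counting interval from 51.96 to 743. The edgeR adjusted p-values of these 4 genes lay between 1.08e-12 and 6.85e-07. In all, 532 of 1656 genes (32.1%) changed, 291 up and 241 down, of which 223 and 196 were at least 2-fold. The majority turned to falls with other scalings and without some embryos: library size alone gave 227 up and 424 down with a median log2 change of -0.22, and DESeq2 size factors gave 265 up and 312 down. With TMM, rises went from 54.7% of the calls to 31.6% of 582 without the embryos at 330 and 340 minutes and to 43.96% without those of 1, 2 and 4 cells. The count was 218 with limma-trend, 816 without the shallow embryos, 1236 without the low-count filter and 116 with the 8 embryos on each side of the border.

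Over the longer interval from the early to the late window, 1125 genes (67.9%) changed, 615 up and 510 down, with 512 and 407 at least 2-fold. CJA18719 had 0 reads early and reached 4760 ± 2898 CPM (SD, n = 14) in the late embryos, so its summed reads were at least 1799.8-fold higher. CJA03873 went on rising to 7396 ± 6408 CPM (SD, n = 14), where 9778 reads stood against 2 in the early library. CJA33872 had 1909 reads early and 0 late, at least 611-fold lower, and CJA32794 went from 1343 ± 1367 CPM (SD, n = 16), or 1835 reads, to 1 read in the late library, a ratio of 1763 with a counting interval from 316 to 69652. The edgeR adjusted p-values of the 4 genes lay between 3.44e-17 and 4.80e-13. With DESeq2 size factors the split was 417 up and 803 down (median log2 change -0.64), and with library size alone 470 up and 696 down (median log2 change -0.37). Without the embryos at 330 and 340 minutes rises were 37.5% of the calls. The count was 1690 without the shallow embryos, 740 with limma-trend and 2665 without the low-count filter. Without the shallow embryos, 937 of the 1003 genes were called again for middle against early, 488 of 532 for late against middle and 1052 of 1125 for late against early, each in the same direction.

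**Figure D3:**
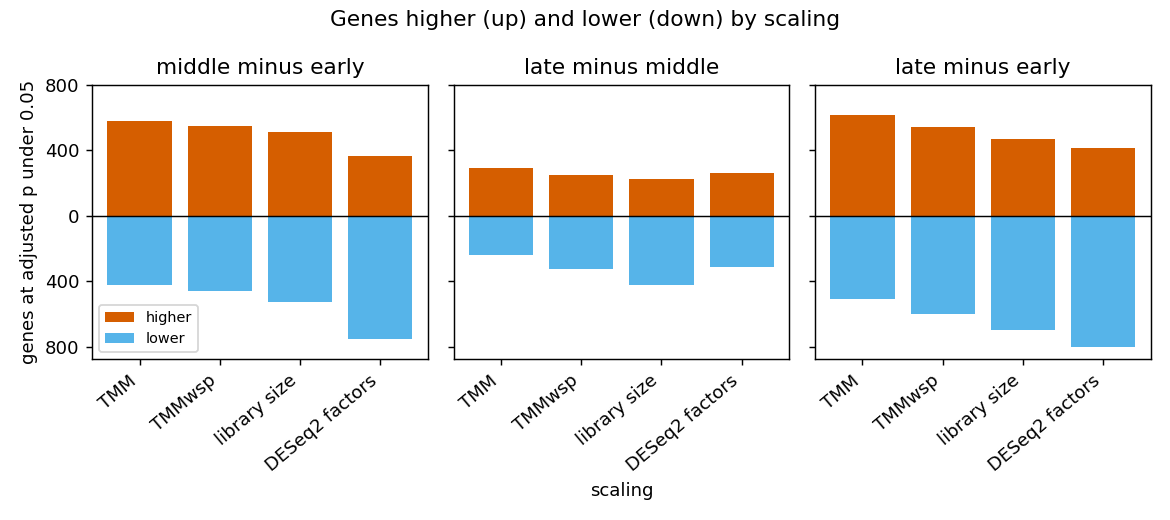
Number of genes at an edgeR adjusted p under 0.05 that were higher (above 0) or lower (below 0) in the later window, for 3 window comparisons and 4 scalings. The split for the middle against the early window goes from 579 higher and 424 lower with TMM to 365 and 750 with DESeq2 size factors.

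**Figure D4:**
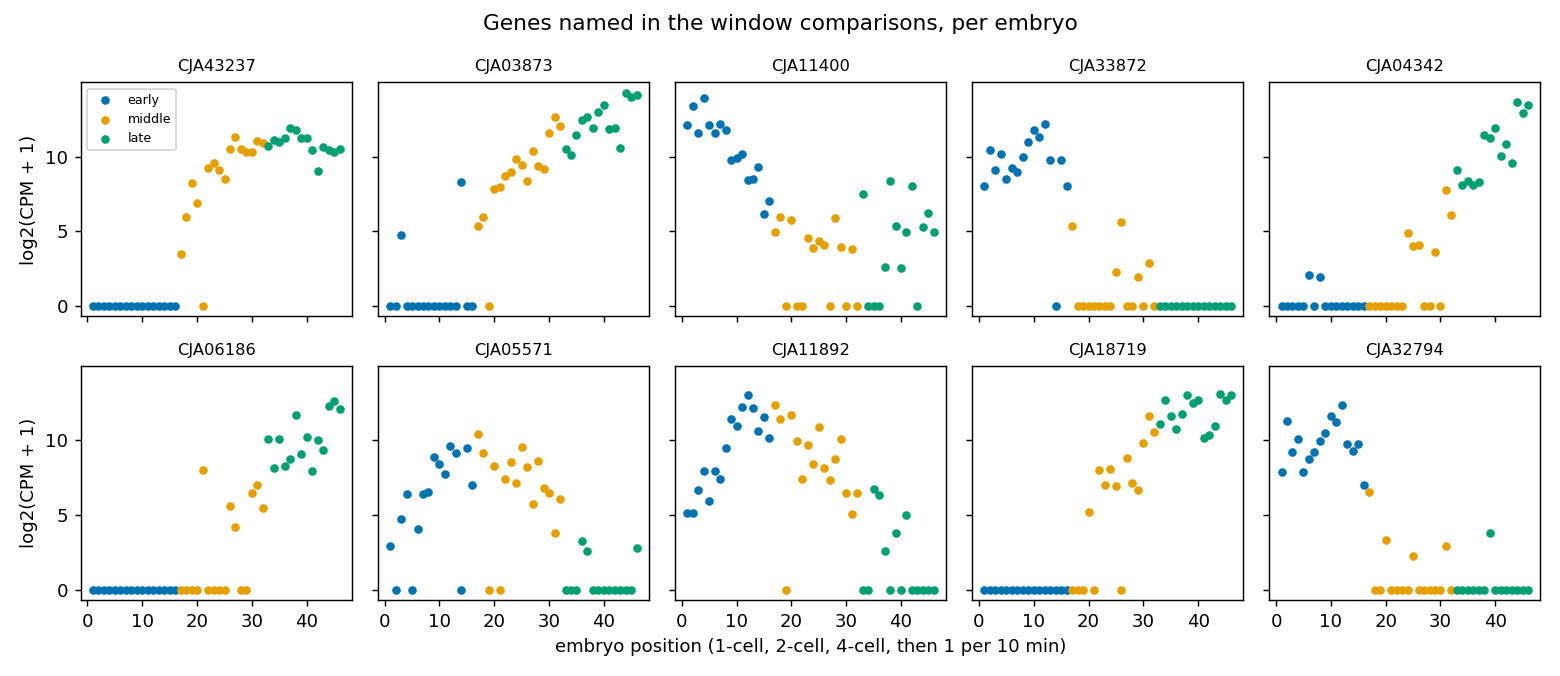
Level of each of the 10 genes named in the window comparisons, as log2(CPM + 1), in each embryo against embryo position, coloured by library. CJA43237, CJA03873, CJA04342, CJA06186 and CJA18719 have 0 reads in most or all early embryos and rise later, while CJA33872 and CJA32794 have 0 reads in most middle and late embryos and CJA11400 falls through the early window and stays at lower levels, with a few late embryos above 180 CPM. The whole late library held 26 reads of CJA11400.

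Slopes within a library are not affected by a constant difference between libraries, but they are tied to the barcodes: barcode numbers rose with time from 1 to 16 in the early library, ran back from 16 to 1 in the middle one and rose in the late one apart from 15 and 16 at 330 and 340 minutes. Time and barcode order therefore cannot be told apart within the early or the middle library. Within the early library most changing transcripts fell: 279 of the 379 genes with a slope fell and 100 rose. CJA11400 went from 8543 ± 5830 CPM in its first 4 embryos to 297 ± 256 in its last 4 (SD, n = 4 each), and CJA21120 from 185 ± 179 to 2.53 ± 5.07 CPM (SD, n = 4 each). The latter rose again to 1255 ± 885 CPM in the late embryos (SD, n = 14). CJA27221 and CJA00344 had 0 reads in the first 4 embryos and reached 317 ± 140 and 185 ± 161 CPM in the last 4 (SD, n = 4 each). These rises rest on 34 and 27 reads in the whole early library. Of the last 4 early embryos, those at 110, 120 and 130 minutes were shallow, with 1890, 14709 and 7443 reads in the listed genes. The last values of the 4 genes therefore rest on few reads in these embryos. The edgeR adjusted p-values of these 4 slopes lay between 6.48e-08 and 4.69e-06, or at 6.94e-10 for CJA27221. Rises made up 26.4% of the calls, 14.3% with DESeq2 size factors and 29.7% with library size alone. Without the embryos of 1, 2 and 4 cells CJA21120 did not pass (edgeR adjusted p = 0.31), nor with rank correlation (0.052), and the count was 181, with limma-trend 167, with rank correlation 241 and without the low-count filter 821. Of the 379 slopes, 268 were called again without the shallow embryos, in the same direction.

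Within the middle library the balance was the other way, with 213 of 293 genes rising and 80 falling. CJA07461 and CJA10728 went from 0 reads in the first 4 embryos to 148 ± 148 and 195 ± 134 CPM in the last 4 (SD, n = 4 each). These rises rest on 30 and 70 reads in the whole middle library. CJA07893 fell from 901 ± 641 to 17.2 ± 34.4 CPM and CJA36436 from 2549 ± 1182 to 38.8 ± 40.4 CPM over the same embryos (SD, n = 4 each). The edgeR adjusted p-values were 1.07e-09 for CJA10728 and between 7.19e-07 and 4.37e-06 for the others. Rises were the majority in each of 4 scalings, at 72.7% with TMM, 65.9% with DESeq2 size factors, 59.6% with TMM with singleton pairing and 55.6% with library size alone, and at 53.3% without the embryos at 330 and 340 minutes. The count was 107 with limma-trend and 499 without the low-count filter, and the fall of CJA36436 did not pass with limma-trend (adjusted p = 0.15) or rank correlation (0.091), nor the rise of CJA07461 with DESeq2 (adjusted p = 0.12).

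Within the late library 121 genes had a slope, 65 up and 56 down. CJA12535 rose from 69.6 ± 139 to 2707 ± 2353 CPM and CJA38116 from 45.6 ± 91.3 to 114 ± 78.7 CPM between the first and last 4 embryos (SD, n = 4 each), with edgeR adjusted p-values of 2.40e-06 and 0.0040. CJA04276 fell from 298 ± 149 to 12.2 ± 17.4 CPM and CJA04132 from 69.6 ± 87.8 CPM to 0 reads in the last 4 (SD, n = 4 each), with edgeR adjusted p-values of 7.12e-04 and 0.0087. The whole late library held 54 reads of CJA38116 and 17 of CJA04132, against 1093 of CJA12535 and 265 of CJA04276. Of the first 4 embryos, those at 300, 310 and 320 minutes were shallow, so the first values of CJA38116 and CJA04132 rest on very few reads. The share of rises was 53.7% with TMM, 34.7% with DESeq2 size factors, 27.8% with library size alone and 92.6% with limma-trend, so the direction of the majority is not set. The count was 182 with DESeq2 and 329 without the low-count filter, and it dropped to 52 without the embryos at 330 and 340 minutes and to 26 with rank correlation. Of the 121 slopes, 52 were called again without the shallow embryos, in the same direction. CJA38116 did not pass with DESeq2 (adjusted p = 0.086), limma-trend (0.18) or rank correlation (0.52), and CJA04132 did not pass with limma-trend (0.14), rank correlation (0.26) or without the embryos at 330 and 340 minutes (0.22).

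Over the whole course, 1345 of 1656 genes (81.2%) varied with position in the spline fit. A minimum early and a maximum late were found in 455 genes with a median range of 3.01 on the log2 scale, and the opposite shape, a maximum early and a minimum late, in 371 genes with a median range of 2.53. Which of the 2 is more frequent is not set, since the order turned to 304 and 604 with DESeq2 size factors, 323 and 545 with library size alone, 406 and 430 with singleton pairing and 573 and 590 without the shallow embryos. With TMM scaling a maximum in the middle window occurred in 235 genes, 154 of them with their minimum early. Of the 595 genes with an early maximum, 298 had it at the 1-cell stage, and of the 515 with a late maximum, 358 had it at 430 minutes. These totals moved too: early, middle and late maxima numbered 930, 154 and 343 with DESeq2 size factors. Without the shallow embryos they numbered 967, 375 and 680. With TMM scaling, the 455 rising genes passed the middle of their fitted range at a median of 180 minutes (quartiles 150 and 220) and the 371 falling ones at 200 minutes (quartiles 160 and 280). These genes were chosen for fitted extremes in the early and the late window, and the curve is smooth across the library borders. Both favour times between these windows, and the times were not taken with other scalings. With the library as a covariate 592 genes varied. The count was 724 with limma-trend, 2022 without the shallow embryos and 3143 without the low-count filter.

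A step at a library border beyond the smooth course was called for 19 of 1656 genes (199 at an unadjusted p under 0.05 with 46 embryos) and for 2 with a spline of 6 degrees of freedom. On simulated counts this test found 2% of 4-fold steps, so the low count does not show that the libraries lacked a difference.

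The use of alternative 3′ end peaks was tested in 454 genes with 959 peaks. In CJA14647 the share of the peak at location 6651 was 1.30% ± 2.50 in the early embryos (SD, n = 6), 89.3% ± 11.6 in the middle ones (SD, n = 10) and 88.5% ± 13.2 in the late ones (SD, n = 6). In CJA16954 the share of the peak at 5346 was 5.33% ± 7.94 (SD, n = 10), 15.4% ± 10.0 (SD, n = 11) and 39.1% ± 23.1 (SD, n = 7) in the same order. In CJA15738 the peak at 466 went from 31.1% ± 10.9 (SD, n = 12) to 7.01% ± 6.46 (SD, n = 14) and 9.22% ± 9.19 (SD, n = 7). In CJA18031 the peak at 3192 went from 19.9% ± 7.45 (SD, n = 15) to 5.86% ± 7.94 in the middle embryos (SD, n = 7), with 4 reads of the gene in the late library. These genes lie outside the rule for named genes and were chosen after their values were seen, as the 2 largest rises and 2 largest falls of the higher-location peak among called genes with 2 tested peaks. Their adjusted p-values lay between 1.88e-04 and 0.0026. In all, 110 peaks in 67 genes (14.8%) changed their share with position, 56 up and 54 down. In the 408 genes with 2 tested peaks, the higher-location peak rose in 204 (50%, exact binomial p = 1), and among the 48 called ones it rose in 24 and fell in 24. Neither direction of location was in excess at any distance between the peaks: the higher-location peak rose in 109 of 209 genes with peaks under 50 apart, in 50 of 99 with peaks 50 to 100 apart and in 45 of 100 with peaks at least 100 apart (exact binomial p = 0.58, 1 and 0.37, adjusted p = 1 for each). Since the direction of the location numbers is not stated, these counts cannot show whether 3′ ends became longer or shorter. With the library as a covariate, the logistic regression called 0 genes, and 67 peaks in 47 genes lay at an unadjusted p under 0.05, so the change of usage is not separable from the libraries. The slope of log odds per position went from 0.175 ± 0.045 to 0.082 ± 0.073 in CJA14647, from 0.079 ± 0.016 to 0.062 ± 0.050 in CJA16954, from -0.059 ± 0.011 to -0.021 ± 0.029 in CJA15738 and from -0.070 ± 0.016 to -0.065 ± 0.025 in CJA18031 (SE). The standard error grew in all 4, and the slopes of CJA16954 and CJA18031 changed by less than that error, so the wider error ended their calls. With the covariate the unadjusted p was 0.22 for CJA16954 and 0.015 for CJA18031, and only the latter missed the threshold through the correction over peaks. No other tool was run on peak shares.

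**Figure D5:**
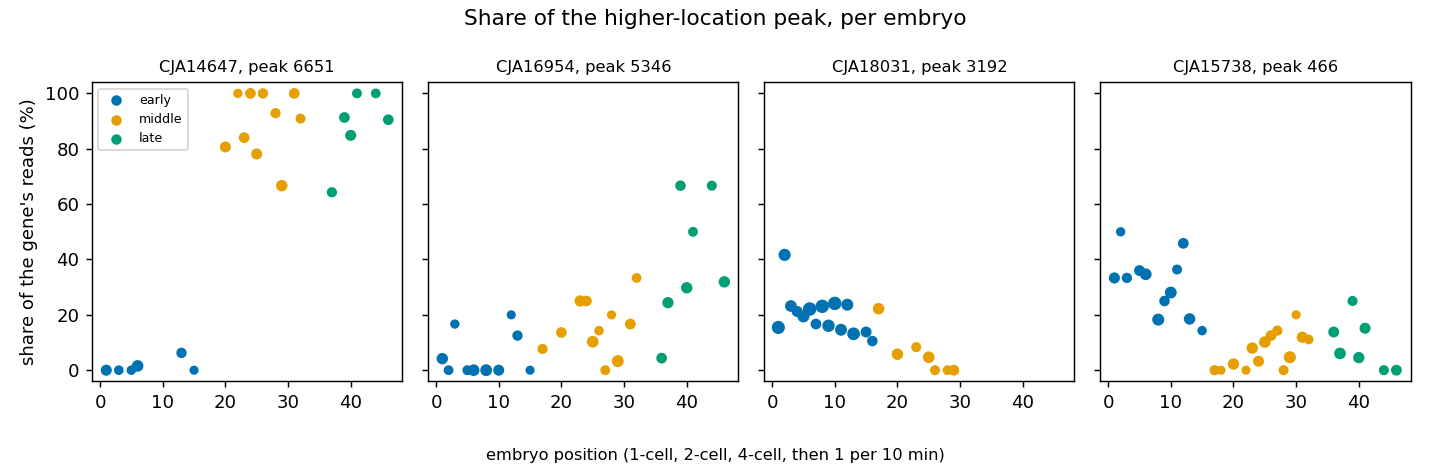
Share of the gene's reads in the higher-location peak of 4 genes, in % for each embryo with at least 5 reads of the gene, against embryo position and coloured by library. Point size grows with the reads. The peak of CJA14647 goes from a mean of 1.30% in the early embryos to 89.3% in the middle ones.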

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

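The comparisons of slopes between libraries and the share of reads outside peaks were not among the tests fixed before the data were examined. Genes whose slope on embryo position differed between libraries were found with the slope difference itself as the tested term in edgeR. Between the early and the middle library 431 of 1656 genes (26.03%) differed, and 300 of them had a negative fitted slope in the early library and a positive one in the middle library, against 84 with the opposite order and 47 with slopes of 1 sign. The excess of genes that fell and then rose held with other scalings, with 378 of 515 genes with DESeq2 size factors, 261 of 459 with library size alone and 252 of 420 with singleton pairing, and without the shallow embryos it was 329 of 611. Between the early and the late library 302 genes (18.2%) differed. Here the direction was not stable: 176 fell early and rose late against 88 with the opposite order, but with library size alone these numbers were 134 and 152. Between the middle and the late library 7.19% of the 1656 genes differed, and 54 had a positive slope in the middle and a negative one in the late library, against 23 with the opposite order. That excess kept its direction in the other scalings and without the shallow embryos (84 against 27, 84 against 25, 44 against 28 and 44 against 32). Barcode numbers ascend with time in the early library, descend in the middle one and ascend again in most of the late one. An effect of barcode order would thus by itself turn slopes between the early and the middle library and back in the late one, so these opposite slopes cannot be assigned to time.

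The comparisons of peaks test only reads that lie in a peak, as a share of the total of the gene. Of the reads counted for the listed genes, 6.70% lay outside any listed peak, with 7.46% in the early, 6.54% in the middle and 6.09% in the late library. There are no control samples to set this share against, and no location is given for these reads.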

How the results depend on the processing

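No correlation of component 1 changed sign under the alternatives run, and no named gene did where it was tested. Some named genes did not pass the filter of a setting and have no value there. With 8 embryos on each side of a border, only CJA04342 and CJA06186 of the genes named for those comparisons were tested. CJA33872, CJA32794 and CJA38116 were not tested without the embryos of 1, 2 and 4 cells, nor CJA07461 without the shallow embryos. CJA07461 and CJA38116 were also not tested without the embryos at 330 and 340 minutes. The majority direction of the called genes did turn. With the scaling it went from 579 up and 424 down to 365 and 750 with DESeq2 size factors for middle against early, from 291 and 241 to 227 and 424 with library size alone for late against middle, and from 615 and 510 to 417 and 803 with DESeq2 size factors for late against early. With TMM but without the embryos at 330 and 340 minutes it turned to falls in all 3, from 57.7%, 54.7% and 54.7% rises to 47.4%, 31.6% and 37.5%, and the cause was not tested. Over all settings the share of rises ran from 32.7% to 67.8%, 31.6% to 68.97% and 34.2% to 54.7%. Counts are listed in the order middle against early, late against middle, late against early, slopes in the early, middle and late library, and whole course. Without a low-count filter (3955 genes) they were 2309, 1236, 2665, 821, 499, 329 and 3143, and with a mean of at least 20 CPM (3915 genes) 2282, 1217, 2630, 821, 495, 324 and 3105, more because more genes were tested. With limma-trend all 7 were lower, at 484, 218, 740, 167, 107, 108 and 724, the late slopes within 1.5 times, and the cause was not tested. DESeq2 gave 182 late slopes. Without the shallow embryos the window counts were 1508, 816 and 1690 and the whole-course count 2022, with more genes past the filter. There were 181 early slopes without the embryos of 1, 2 and 4 cells, 52 late slopes without those at 330 and 340 minutes, and 168 and 116 genes with 8 embryos on each side of the borders, settings that change both the number and the ages of the embryos. Rank correlation gave 241 early and 26 late slopes, the spline of 6 degrees of freedom 2 steps and the library covariate 592 whole-course genes, and the cause of these changes was not tested. Peak usage was called for 0 genes with the library as a covariate and for 23 of 131 genes with peaks at least 100 apart, where fewer genes were tested. The other 68 values of these results stayed on their side of the threshold or within 1.5 times, as did 273 values for single genes, slope differences and course shapes, while 15 kept their direction but missed the threshold. The genes with a maximum early and a minimum late rose from 371 to 604 with DESeq2 size factors and 590 without the shallow embryos. TMM with singleton pairing, 3 usage settings and all settings for slope differences and course shapes were chosen after seeing the data. The list tests, the repeat embryos and the settings for normalized units could not be run, since the table has no names, no repeats and only counts. At the depth of these embryos, 8% to 29% of 4-fold slopes and 2% of 4-fold steps were found on simulated counts.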

Other observations

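Chosen only after the result was seen were the measures of this and the next paragraph, the random orders for peak usage, the moved borders for the step, the tests of barcode, of distinct transcripts and of close peaks, and the orders that replaced a binomial test. The spread of reads over genes differed between the windows. With 39 embryos of at least 10000 reads thinned to 10000 reads each, the 10 most abundant genes of an embryo took 7.73% ± 1.25 of the reads in the early window (SD, n = 14), 10.1% ± 1.92 in the middle (SD, n = 14) and 11.1% ± 1.25 in the late window (SD, n = 11). The middle window lay above the early one (permutation p = 7e-04, adjusted p = 0.0021 over 6 comparisons), as did the late one (permutation p = 1e-05, the smallest they can give, adjusted p = 6e-05), while the middle and late windows did not differ beyond their spread (permutation p = 0.13, adjusted p = 0.21). These windows are also libraries. Within the early library the share of the top 10 genes also rose with position, with rho 0.66 (n = 14, permutation p = 0.013, adjusted p = 0.025 over 6 correlations) and r 0.60 (permutation p = 0.023), and r 0.63 without the 2 embryos farthest from the middle of the window. Position there is also the barcode order, so this trend cannot be assigned to time. No trend was found in the middle library (rho 0.24, permutation p = 0.41, r 0.06, permutation p = 0.83, n = 14, r 0.06 without the 2 farthest embryos). In the late one the values depended on 2 embryos (rho 0.16, permutation p = 0.63, r 0.18, permutation p = 0.59, n = 11, but r 0.58 without the 2 farthest), so a trend there is left open.

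The number of listed genes detected at 10000 reads fell along the early library and rose along the middle one. It was 2243 ± 165 early (SD, n = 14), 2181 ± 81.6 in the middle (SD, n = 14) and 2160 ± 72.6 late (SD, n = 11), with no difference between windows beyond their spread (permutation p between 0.14 and 0.51). The unthinned numbers in these embryos were 3140 ± 423, 3333 ± 486 and 3357 ± 565 (SD). Within the early library it fell with position, with rho -0.71 (n = 14, permutation p = 0.0052, adjusted p = 0.021) and r -0.66 (permutation p = 0.012), and r -0.59 without the 2 embryos farthest from the middle of the window. Within the middle library it rose, with rho 0.70 (n = 14, permutation p = 0.0071, adjusted p = 0.021) and r 0.71 (permutation p = 0.0043), and r 0.60 without the 2 farthest embryos. The late library showed no trend (rho 0.23, permutation p = 0.50, r 0.10, permutation p = 0.77, n = 11). Barcode order is reversed between the early and the middle library, so the mirrored trends are also a single trend along barcode number and cannot be assigned to time. The listed genes were selected on reads, and the effect of that selection on these trends was not tested.

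Random regroupings of the embryos argue against chance for the counts listed here, except the step at a border. The smallest share that 100 regroupings can give is 1 of 100, the real one. Of 100 assignments of the embryos to groups of the same sizes, real one included, 1 gave as many genes as the real windows: 1003 against at most 0 in the others for middle against early, 532 against at most 103 for late against middle, and 1125 against 18 for late against early. These random groups mix embryos of all ages. They test only whether the counts are unrelated to time and library, and not where the windows are divided. Of 100 orders of the embryos within their libraries, 1, the real one, gave as many slopes: 379 against at most 62 in the early library, 293 against 132 in the middle and 121 against 15 in the late. The same orders gave at most 28 slope differences between the early and middle libraries against the real 431, at most 19 between early and late against 302, and at most 61 between middle and late, where the real order gave 24 genes with a higher and 95 with a lower slope in the late library. In each of these 3 cases 1 of the 100 orders, the real one, gave as many. With the order of all embryos shuffled, 1 of 100 orders, the real one, gave as many whole-course genes, 1345 against at most 14. For peak usage 1 of 100 orders of all embryos, the real one, gave as many genes, 67 against at most 3. For the step at a border, 1 of the 100 random assignments gave as many genes, 19 against at most 4, but they break up the stretches of time that the libraries hold, so they do not test it. After that result was seen, both borders were instead moved along the time order: 1 of 25 positions, the real one, gave as many genes, 19 against at most 17, which came with the borders moved by 1 embryo. These positions share most of their embryos and have other group sizes, and the spline of 6 degrees of freedom called 2, so chance or a misfit of the spline is not excluded for the 19 genes.

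Component 1 jumped at the border of the early and middle libraries. The mean of the 4 embryos after 130 minutes lay above that of the 4 before by 31.2% of the whole range of component 1, the largest of 39 such positions, whereas the border at 290 minutes gave 1.55% and ranked 29, or 10.7% and 15 of 32 positions after thinning to 10000 reads. With the 39 embryos thinned in this way, the nearest cut lay after 120 minutes. It gave 42.8% of the range, the largest of the 32 positions. The embryos at 110, 130, 160 and 180 minutes fell under 10000 reads and were left out. This cut therefore spans a wider stretch of time than the unthinned one, and its score used another log transform. A difference across the border thus remained at equal depth, but whether low depth adds to the jump after 130 minutes stays open. A library difference as the whole cause stays open: of 165 genes called between the 8 embryos on each side, 70.9% had slopes within the libraries that went the way of the jump, but random orders within libraries gave up to 78.2%, and the library changes where the time does. A fast change of the transcriptome between 130 and 140 minutes may also account for it and cannot be told apart from the library with these embryos.

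A further axis was sought in the variation left after time was removed: in the 29 embryos with at least 40000 reads, after a spline of position was removed from each of 3937 genes, the leading component of what remained held 20.7% of the variance and the next 9.88%. That it does not follow time was set by removing the spline and is not a finding. The score of this component was -40.4 in the 2-cell embryo, -47.3 at 240 minutes and -49.3 at 350 minutes, and between -28.04 and 18.7 in the others. The 20 genes with the largest loadings had a mean of 4.89 log2 CPM at 240 minutes against 8.61 at 260 minutes in the same library. These genes were chosen by their loadings in the same embryos, so the difference illustrates the axis and adds no support for it. The score was correlated with the log2 number of reads (rho 0.53, permutation p = 0.0032, r 0.48, permutation p = 0.0079, and 0.45 without the 2 embryos farthest from the median depth). The number of reads as such is argued against, as the scores with all embryos thinned to 40000 reads correlated with the unthinned ones at rho 0.976 and r 0.993 (permutation p = 1e-05 for both, the smallest they can give, and r 0.993 without the 2 farthest embryos). Noise that is independent from gene to gene is argued against too: the gene loadings of the 3 libraries taken alone correlated across genes at a median rho of 0.467, against at most 0.027 with residuals shuffled for each gene. That shuffle also removes any effect shared by the genes of 1 embryo, so it does not argue against such an effect. Still open is the barcode. It held 47.7% of the score's variance with a permutation p of 0.551. Most of 10000 shuffles of the barcodes gave as large a share, so this share is no evidence for a barcode effect. A lower capture of distinct transcripts is also open. Embryos with low scores had fewer genes detected at 40000 reads over all genes (rho 0.54, permutation p = 0.0026, r 0.65, permutation p = 1.2e-04, and 0.60 without the 2 farthest embryos). That count includes the genes behind the score. The 1968 genes with small loadings gave rho -0.041 (permutation p = 0.83) and r -0.14 (permutation p = 0.46, and 0.05 without the 2 farthest embryos). These genes were chosen because they follow the score little, which favours a value near 0, so they do not decide the question. No biological explanation was tested, because the labels give neither the sex nor the mother of an embryo.

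The calls of changed peak usage ended when the library was a covariate. In the called genes the slope within libraries had a median of 0.36 of the slope over all embryos, and it went the same way in 43 of 67 genes, or 64.2%. An exact binomial test against 50% gave p = 0.027, but it takes genes that share the same embryos as independent: 9 of 100 orders of the embryos within libraries, the real one included, gave as high a share, up to 74.6%. A library difference as the whole cause therefore stays open, as does a change with time. Close peaks that are not separate 3′ ends are argued against as the whole cause, since 14% of the 100 genes with 2 peaks at least 100 apart were called, 14 genes against at most 1 in the other 99 of 100 random orders of all embryos, next to 10.5% of those with peaks under 50 apart.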
